A study of Macaca mulatta with 5 samples.

How the data were processed

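Single-cell RNA sequencing (10x Genomics, 3' version 3) was carried out by the authors on cortex-enriched fetal rhesus kidney cells, per the labels' protocols. Cell Ranger 6.0.1, Seurat and the build hg19 are named in the submitters' processing notes, with no role or order. Cell filters, doublet handling, the method of integration and the clustering settings are not given in the sources used here. The deposited file is 1 table with a row per cell, holding the authors' cluster name, the library name, the species and the position in the authors' UMAP embedding, an arbitrary two-dimensional layout of the integrated data, per the file headers. It gives no gene values, counts per cell, genes per cell or mitochondrial shares, so depth could not be assessed and clusters could not be re-derived. The names come from an integration of rhesus with human cells, per the series' design text, so cluster membership also depends on libraries that were not used here.

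Rows were used only where the library name matched a sample number in the titles, which gave 5 libraries and 36039 cells. The table holds 11 further library names with 58227 rows, which were not analysed here, so no comparison between species was made. Of the cells used, 5 share their identifier with a row of another library, and no identifier was repeated among the 5 libraries. Libraries 600 and 628 were grouped as dissected, and 623, 627 and 632 as vortexed, because the extraction protocol names these numbers. Gestational age and sequencing batch per library were not given in the labels, so neither can be told apart from the preparation. The dissected pair came from 2 donor kidneys, per the labels' protocols, but nothing states that all libraries come from separate animals, so p-values measure only the spread between these libraries, which may be technical. No libraries were duplicates: each pair differed by a chi-square of at least 25.3 per degree of freedom.

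The 37 cluster names were joined into 10 classes by name alone. This was planned for before any share was computed, but the classes were written down after the table of cells per cluster and library had been seen. The phase class and the unplaced epithelium were not among the planned classes. NPC and Cap mesenchyme formed the nephron progenitors, and both Differentiated NPC clusters with Broad proximal diff formed the early nephron. The 4 Proximal tubule clusters with Loop of Henle, Thick ascending limb and Distal convoluted tubule formed the tubule. Collecting Duct and both Intercalated cell clusters formed the collecting duct class. Fibroblast, Interstitial and Stromal-Microvascular clusters formed the stroma. The 4 endothelial clusters and the 7 leukocyte clusters formed the endothelium and immune classes, Podocyte formed its own, and clusters named M-phase or G2-M phase were kept as a phase class because their names give no lineage. Epithelial (c23) was left as unplaced epithelium. Nephron lineage means progenitors, early nephron, podocytes and tubule, 13 clusters.

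Cells were counted per cluster and library. Shares are given with exact (Clopper-Pearson) 95% intervals for single libraries and as mean ± SD over libraries, each with equal weight. A count of 0 of 2553 cells, the smallest library, allows a share of up to 0.118%, and 3 cells was taken as this limit. The planned main test between preparations was a count model. Because the deposited file holds no count column, the fallback fixed in advance took its place, which was limma 3.58.1 (R 4.3.3) on log2 odds of the share with 0.5 cells added, for clusters with at least 10 cells, with Benjamini-Hochberg adjustment over clusters and a threshold of 0.05. Class shares were compared by an exact permutation test over the 10 splits, and ratios within libraries by an exact sign-flip test over 32 sign patterns. Which 5 ratios to test, the composition distances between libraries, the count of non-overlapping clusters and the analysis of neighbours were added after the data were examined. The limma step was tested on 100 simulated data sets of 37 clusters with known changes in some of them. Each library kept its number of cells, so the changes also shifted the shares of unchanged clusters. The limma step called 1.31% of unchanged clusters at the adjusted threshold, and 8.03% of them had an unadjusted p below 0.05.

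Clusters were named in the text by a rule set before the data were examined: clusters past the threshold, the 5 most abundant and the nephron-lineage clusters. The planned results on depth, on quality per cluster and on cell cycle scores could not be computed, since the table has no such columns. Positions in the embedding were used only for neighbours: for each cell, the 15 nearest cells of the same library with another cluster name and not named by phase, in libraries with at least 20 cells of the cluster, with 5 and 50 neighbours as alternatives. Alternatives for the other results covered the transform, the denominator, the filter on cell number, cluster names without their numbers, cells pooled over libraries, podocytes left out of the lineage and leaving out each library. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used.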

Results

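The data describe single cells from cortex-enriched kidneys of fetal rhesus macaques, taken between the late second and the third trimester, while the kidney is still forming nephrons. The cells of 5 libraries were analysed. In 2 libraries, 600 and 628, the cortex was dissected by hand before a cold enzyme digestion. In the other 3 libraries, 623, 627 and 632, kidneys were vortexed in a cold mix named for Bacillus licheniformis, a bacterium whose protease works in the cold, to release mainly cortical cells. The deposited table held 6839 cells for library 600, 6329 for library 628, 9816 for library 623, 10502 for library 627 and 2553 for library 632, or 36039 cells in all. Each cell carried 1 of 37 cluster names given by the study. The table gave no counts per gene or per cell, so sequencing depth is unknown and the values reported are shares of cells.

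Nephron-lineage cells made up 56.0% ± 8.76 of a library (SD, n = 5), with a range of 46.0% to 67.7%. By the mean over libraries, cells named tubule were the largest class, at 23.7% ± 4.29, although they were the largest in only the 2 dissected libraries. Stroma followed at 18.1% ± 7.47, clusters named only by a cell cycle phase at 13.5% ± 9.18, and nephron progenitors, the self-renewing cells that give rise to the nephron epithelium, at 13.4% ± 9.77. Early nephron cells, the differentiating progeny of the progenitors, made up 13.0% ± 4.10 and collecting duct cells 6.11% ± 3.51. Podocytes, the filtering epithelium of the glomerulus, made up 5.94% ± 6.64, immune cells 3.93% ± 3.36, epithelium with no further name 1.68% ± 0.276 and endothelium 0.604% ± 0.370. Of the single clusters, the 5 most abundant were NPC (c25) at 9.80% ± 9.94, Proximal tubule (c18) at 8.98% ± 3.04, Interstitial Cell Lineages (c16) at 7.40% ± 6.82, G2-M phase (c29) at 6.77% ± 5.62 and Podocyte (c20) at 5.94% ± 6.64. In the same order, the most extreme libraries differed 32.6-fold, 2.13-fold, 5.04-fold, 8.26-fold and 7.85-fold in these 5 clusters. In the authors' embedding, stroma made up 81.2% ± 9.68 of the nearest differently named cells of NPC (c25).

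**Figure D1:**
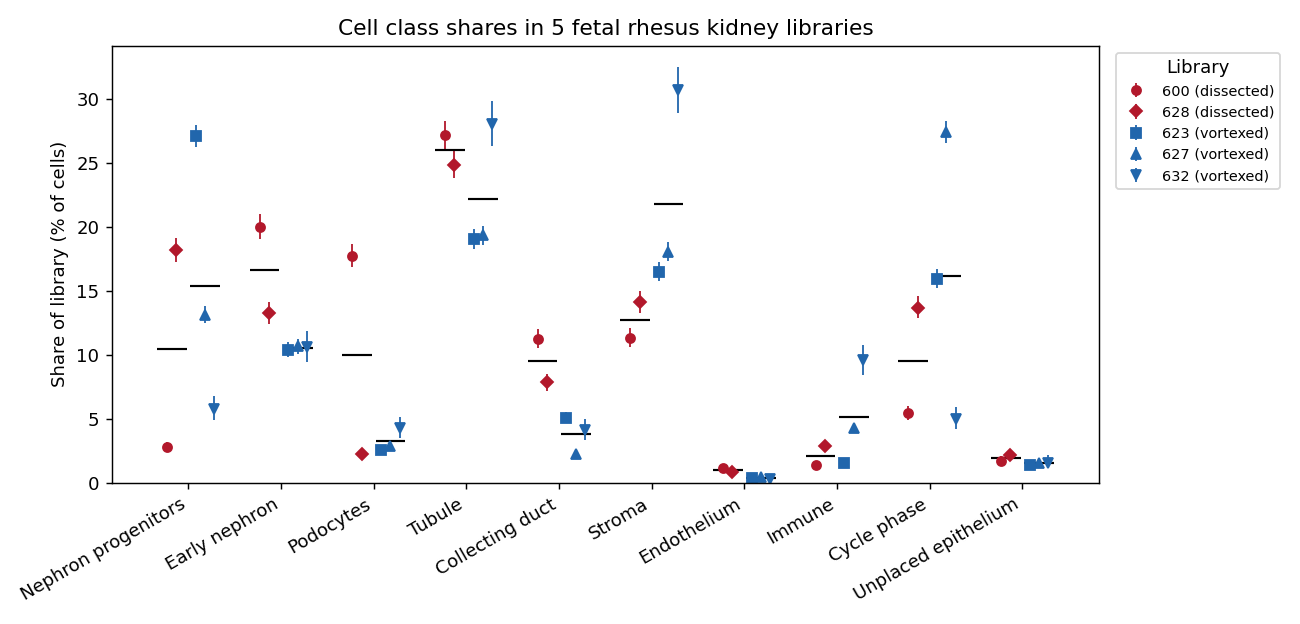
Share of each library's cells (vertical axis, percent) in 10 cell classes (horizontal axis); each point is 1 library, its bar the exact 95% binomial interval, and each black line the mean of a preparation. The endothelial shares of the dissected libraries, 1.16% and 0.806%, lie above those of the vortexed libraries, while library 600 stands apart in podocytes at 17.7%.

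Replicate libraries of 1 preparation differed far more than counting error allows. In dissected library 600, NPC (c25) made up 0.760% of the cells (exact 95% binomial interval, 0.568 to 0.996), against 13.4% (12.6 to 14.3) in dissected library 628, a 17.7-fold difference. Podocytes went the other way, with 17.7% (16.8 to 18.7) in library 600 and 2.26% (1.91 to 2.66) in library 628, 7.85-fold apart. Among the vortexed libraries, NPC (c25) made up 24.8% of library 623, 8.82% of library 627 and 1.18% of library 632, and podocytes 2.56%, 2.86% and 4.27%. Library 632 held the largest shares of Interstitial Cell Lineages (c16), 19.6%, and of immune cells, 9.56%. The smallest chi-square over the 10 pairs of libraries was 25.3 per degree of freedom, for libraries 628 and 623, which were prepared differently, and the value for 600 and 628 was 76.2. Binomial intervals cover counting error only.

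Within the nephron lineage, proximal tubule cells outnumbered distal nephron cells (loop of Henle, thick ascending limb and distal convoluted tubule together) in 5 of 5 libraries, from 2.37-fold in library 628 to 12.8-fold in library 627. The mean log2 ratio was 2.43 ± 1.00 (SD, n = 5; exact two-sided sign-flip test, p = 0.0625, the smallest that 5 libraries allow; Benjamini-Hochberg adjusted p = 0.156 over 5 ratios). Early nephron cells outnumbered podocytes in 5 of 5 libraries, with a mean log2 ratio of 1.59 ± 0.91 (exact p = 0.0625, adjusted p = 0.156), although in library 600 the ratio was only 1.13-fold. Progenitors were 2.60-fold as frequent as early nephron cells in library 623 and 0.139-fold as frequent in library 600, and the mean log2 ratio of -0.32 ± 1.63 could not be told from 0 (exact p = 0.75, adjusted p = 0.75). Most progenitors in libraries 628, 623 and 627 were NPC (c25), whose neighbours in the embedding were 81.2% stroma. Cap mesenchyme (c30) alone held 138, 299, 228, 452 and 118 cells in libraries 600, 628, 623, 627 and 632. Early nephron cells numbered 1370, 839, 1022, 1119 and 271 there, more than c30 in each library. The ratio was not tested without NPC (c25). Progenitors exceeded podocytes in 4 of 5 libraries, all except library 600 (mean log2 ratio 1.27 ± 2.48, exact p = 0.3125, adjusted p = 0.391). Collecting duct (c13) cells exceeded intercalated cells, the acid-base regulating cells of the duct, in 4 of 5 libraries, again except library 600 (mean log2 ratio 0.40 ± 0.58, exact p = 0.1875, adjusted p = 0.3125). No ratio passed an adjusted p of 0.05, and the 5 ratios were chosen after the cell counts had been seen. With 1 library left out, the mean log2 ratio of progenitors to early nephron cells turned to 0.32 (without library 600), that of progenitors to podocytes ranged from 0.74 (without 623) to 2.26 (without 600), and that of collecting duct to intercalated cells from 0.22 (without 628) to 0.62 (without 600).

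**Figure D2:**
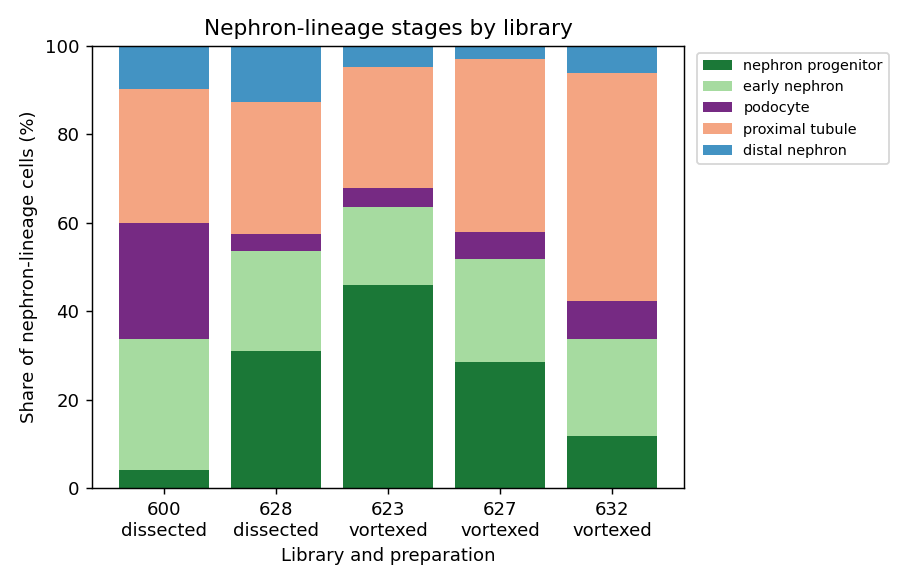
Nephron-lineage cells of each library divided into 5 stages (vertical axis, percent of the library's nephron-lineage cells; horizontal axis, library and preparation; each bar is 1 library). Progenitors run from 4.10% in library 600 to 45.9% in library 623, and proximal tubule exceeds distal nephron in each bar.

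As a share of nephron-lineage cells, progenitors made up 24.3% ± 16.5 (SD, n = 5), early nephron cells 23.0% ± 4.30, podocytes 9.87% ± 9.32, proximal tubule 35.7% ± 9.83 and distal nephron 7.24% ± 3.88. The podocyte mean rested largely on library 600, with 26.2%, against 3.86% to 8.76% in the other libraries. Progenitor shares overlapped between the preparations. They were 4.10% and 31.0% in dissected libraries 600 and 628, and 45.9%, 28.5% and 11.9% in vortexed libraries 623, 627 and 632. Of these progenitors, NPC (c25) held the larger part in libraries 628, 623 and 627, and Cap mesenchyme (c30) in libraries 600 and 632. Distal nephron shares did not overlap, with 9.72% and 12.6% in the dissected libraries and 4.67%, 3.04% and 6.18% in the vortexed libraries. This difference in distal share was not tested on its own, and it was singled out after its values were seen.

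The protocols imply a comparison of hand dissection with vortexing. By class, the dissected libraries had higher mean shares of collecting duct (9.55% ± 2.42, n = 2, against 3.82% ± 1.44, n = 3), early nephron (16.6% ± 4.79 against 10.6% ± 0.131) and endothelium (0.980% ± 0.247 against 0.353% ± 0.0821), and lower mean shares of stroma (12.7% ± 1.95 against 21.8% ± 7.79). The 2 dissected and 3 vortexed values did not overlap for these 4 classes or for unplaced epithelium (1.93% ± 0.288 against 1.51% ± 0.0856). That is 5 of 10 classes, where chance gives 2. Values overlapped for progenitors (10.5% ± 10.9 against 15.3% ± 10.8), podocytes (10.0% ± 10.9 against 3.23% ± 0.915), tubule (26.03% ± 1.62 against 22.2% ± 5.14), immune cells (2.11% ± 1.04 against 5.14% ± 4.06) and phase-named clusters (9.55% ± 5.86 against 16.1% ± 11.2). No class difference could be called: 2 libraries against 3 give 10 splits and an exact permutation p of at least 0.1, which collecting duct, early nephron, endothelium and unplaced epithelium reached (two-sided, Benjamini-Hochberg adjusted p = 0.25 over 10 classes), while stroma gave p = 0.3 and adjusted p = 0.5. Without c16, only 1.97% of whose neighbours in the embedding were stroma, the stromal shares still did not overlap (6.46% and 10.2% against 12.4%, 13.5% and 11.1%). Without Fibroblast (c26), of whose neighbours 21.3% were stroma, they did (9.99% and 10.4% against 10.2%, 10.8% and 27.9%), and without library 632 the stromal difference, -9.03 points, was -4.56. The podocyte difference turned from 6.77 percentage points higher in dissected libraries to -0.97 without library 600. The progenitor difference, -4.87 points, turned to 2.82 without library 600 and to 1.02 without library 623, and the early nephron difference, 6.08 points, was 2.70 without library 600. The difference in unplaced epithelium, 0.414 points, was 0.211 without library 628. The differences in phase-named clusters (-6.57 points), immune cells (-3.03) and tubule (3.88) also depended on single libraries, with -0.924 without 627, -0.818 without 632 and 6.85 without 632.

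By single cluster, 0 of the 37 clusters passed an adjusted p of 0.05 in limma on the log2 odds of the share. In the same test, 5 had an unadjusted p below 0.05, all 5 with a higher share in the dissected libraries. With the centred log-ratio, 3 such clusters were higher and 1 was lower, and the same counts arose without library 623. Without library 632, 5 were higher and 1 was lower. In simulated data where other clusters had been changed, 8.03% of unchanged clusters had an unadjusted p below 0.05. Among the 5 clusters of the main analysis, Thick ascending limb (c12), the salt-reabsorbing part of the loop, made up 3.83% and 4.16% of the dissected libraries and between 0.457% and 1.16% of the vortexed libraries (log2 odds ratio 2.27, SE 0.72, limma adjusted p = 0.176). Differentiated NPC (c19) gave 1.54 (SE 0.66, limma adjusted p = 0.361), with 9.20% and 5.77% against 2.35% to 3.17%. The other 3 had endothelial or microvascular names and lay outside the naming rule, chosen after their values were seen. Stromal-Microvascular (c4) was counted in the stroma class, not in the endothelium. Stromal-Microvascular (c4) gave 3.08 (SE 0.78, limma adjusted p = 0.114), Endothelial cell (c2) 2.51 (SE 0.67, limma adjusted p = 0.114) and Endothelial (c5) 2.12 (SE 0.91, limma adjusted p = 0.361). These 3 clusters held 79, 17 and 90 cells in all, and library 600 supplied 65.8%, 52.9% and 68.9% of them. Endothelial cell (c2) was found in 0 of the 2553 cells of library 632, which allows a share of up to 0.118%.

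The remaining nephron-lineage clusters lay on both sides of 0, with none past the threshold in limma. Podocyte (c20) gave a log2 odds ratio of 1.12 (95% interval -1.19 to 3.43), Loop of Henle (c15) 1.35 (-0.36 to 3.05), Distal convoluted tubule (c10) 0.70 (-0.97 to 2.37) and Proximal tubule (c8) 0.59 (-0.89 to 2.08). Broad proximal diff (c17) gave 0.35, Proximal tubule (c6) 0.30, Proximal tubule (c7) 0.25 and Differentiated NPC (c14) 0.09. Values below 0 were found for NPC (c25), -1.07 (-4.87 to 2.73), Proximal tubule (c18), -0.48 (-2.11 to 1.14), and Cap mesenchyme (c30), -0.22 (-1.94 to 1.49). With nephron-lineage cells as the denominator, c14, c6 and c7 gave -0.23, -0.013 and -0.071, and with the centred log-ratio c14 and c7 gave -0.16 and -0.012. Of the other abundant clusters, Interstitial Cell Lineages (c16) gave -0.79 (-2.91 to 1.32) and G2-M phase (c29) -1.04 (-3.46 to 1.38). Without library 600, the values turned to -0.49 for Podocyte (c20), 1.09 for NPC (c25) and 0.41 for Cap mesenchyme (c30), and without library 632 to 0.018 for Interstitial Cell Lineages (c16). In data simulated with the spread of these libraries, limma called 60% of clusters changed 16-fold, 41% of those changed 8-fold, 16.5% of those changed 4-fold and 2% of those changed 2-fold.

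**Figure D3:**
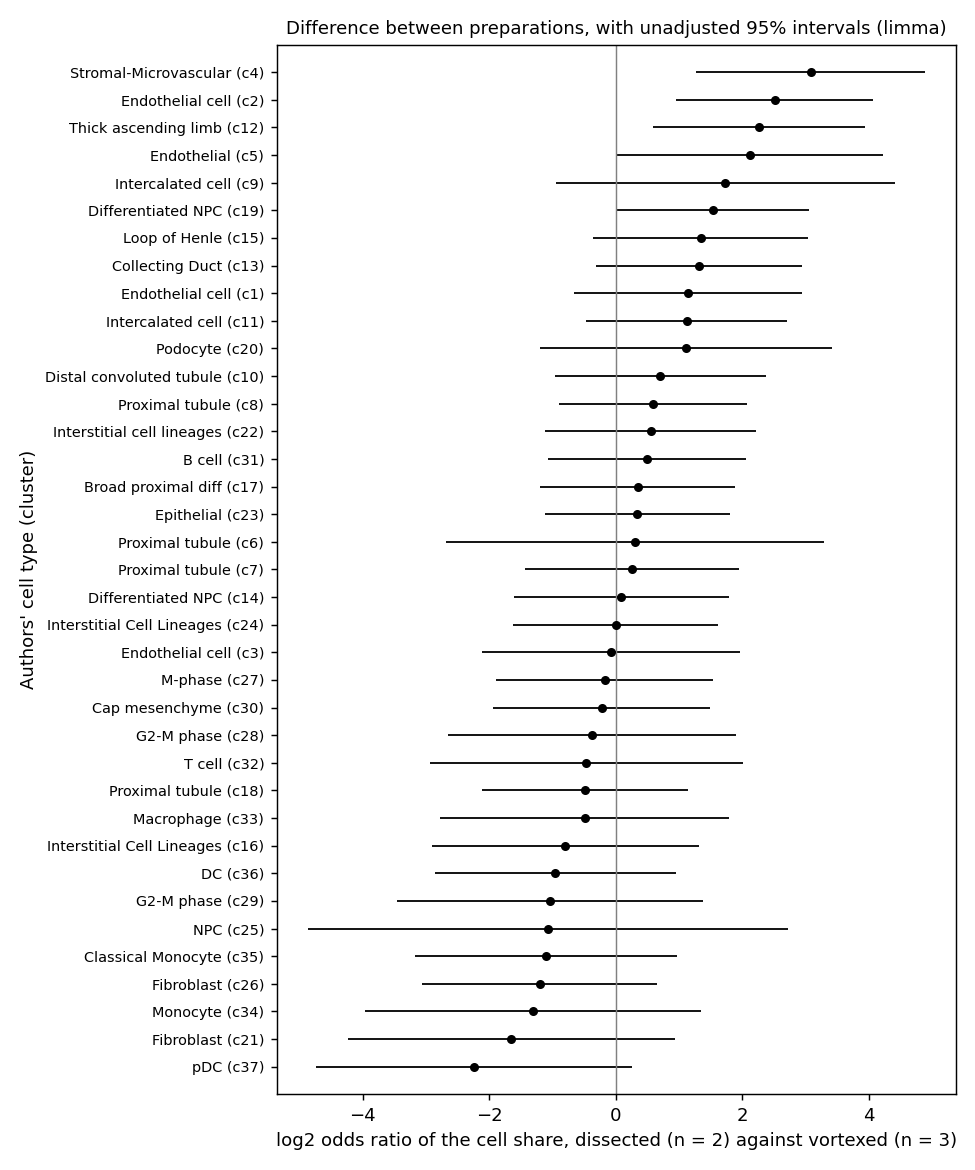
Log2 odds ratio of each cluster's share in dissected (n = 2) against vortexed (n = 3) libraries (horizontal axis) for the 37 clusters (vertical axis); points are limma estimates and bars unadjusted 95% intervals. Stromal-Microvascular (c4) lies highest at 3.08, and no cluster passes an adjusted p of 0.05.

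Across all 37 clusters, the split by preparation took up 34.1% of the variation in composition between libraries on the centred log-ratio scale. Any split takes up some of this variation. Of the 10 splits of the libraries, the real one included, 2 gave a pseudo-F as large as the observed 1.56 (exact permutation p = 0.2). The split that set libraries 600 and 632 against the others gave the highest value, 1.83. The mean distance between libraries was 8.84 for the 4 pairs of the same preparation and 9.67 for the 6 pairs of different preparations.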

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

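The shares compared in the report do not use the positions in the embedding. The Results do cite neighbours of NPC (c25), c16 and c26, and give the stroma without c16 or c26. All tests in this part were chosen after these positions had been seen. Each value is the mean over libraries of the share of a cell's 15 nearest differently named cells, and what drew attention is that it lies far from the share of the same names among all reference cells of the library.

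Cells named Interstitial Cell Lineages (c16) lay away from the other stroma. Only 1.97% ± 1.16 (SD, n = 5) of their neighbours were stroma, against 14.0% among all reference cells, and the neighbours were mainly collecting duct (30.2%, against 7.44%), early nephron (30.4%, against 16.2%) and nephron progenitors (29.3%, against 17.2%, but above their reference share in only 3 of 5 libraries). In each library, stroma was at least 3.93 times rarer among the neighbours than among reference cells. A single library therefore does not explain the rarity of stroma. The same contrast drew attention to c16, so it is no independent test of the abundance of the names. Epithelial or progenitor names made up at least 95.9% of the neighbours in each library, against 72.2% to 90.0% of reference cells. They made up at most 35.1% of the neighbours of the stromal cluster Fibroblast (c21), but stromal clusters varied widely. Stroma made up 82.2% of the neighbours of c21, 71.8% for Interstitial cell lineages (c22), 31.8% for Interstitial Cell Lineages (c24) and 21.3% for Fibroblast (c26). For Stromal-Microvascular (c4) it made up 0%, in 1 library, where endothelium made up 97.7% of the neighbours. A candidate explanation is that the c16 cells are epithelial or progenitor-like under a stromal name, which cannot be told apart from a true interstitial population because 0 of the columns hold gene values. Leaving c16 out of the stroma did not end the separation of the preparations by stromal share, with 6.46% and 10.2% in dissected and 12.4%, 13.5% and 11.1% in vortexed libraries.

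The clusters named by phase lay beside nephron progenitors. Progenitors made up 59.9% ± 12.5 of the neighbours of M-phase (c27), 57.5% ± 18.6 for G2-M phase (c28) and 52.3% ± 9.41 for G2-M phase (c29), against 16.1% of reference cells, in 5 of 5 libraries each. The smallest enrichment over clusters and libraries was 1.97-fold, so a single library does not account for it. With 5 or 50 neighbours the smallest was 1.89-fold, so the number of neighbours does not either. The same contrast with reference cells drew attention to these clusters, so it is no independent test of the abundance of progenitors. These clusters may hold dividing progenitors, a reading that rests on the names NPC (c25), at 30.5%, 39.0% and 39.2% of the neighbours of c27, c28 and c29 and with 81.2% stroma among its own, and Cap mesenchyme (c30), at 29.4%, 18.5% and 13.0%. Stroma made up 19.5%, 20.9% and 21.9% of the neighbours of c27, c28 and c29, near its 21.0% of reference cells. In library 632, stroma exceeded progenitors among the neighbours of c28 (36.8% against 33.3%). Dividing cells of several lineages drawn together by cycle genes remain open, since phase clusters lay 1.42 times as far from other names as the other clusters did, which decides neither way.

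In Fibroblast (c26), nephron progenitors made up 48.0% ± 28.8 of the neighbours against 17.2% of reference cells, with a range of 16.8% to 76.9% over libraries. Stroma made up 21.3% ± 10.7 against 16.7%, but lay above its reference share in only 2 of 5 libraries. In Monocyte (c34), Proximal tubule (c6) made up 43.2% ± 32.3 of the neighbours (n = 4 libraries) against 1.67% of reference cells, with a range of 1.21% to 75.3%. Immune cells made up 37.7% ± 33.3 against 3.75%, above their reference share in 4 of 4 libraries. In library 627, with only 22 cells of c34, immune cells made up 86.7% of the neighbours and c6 1.21%.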

How the results depend on the processing

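The centred log-ratio, the arcsine transform, the denominator without phase clusters, the removal of cells with a shared identifier, the stroma without c16, c26 or both, and the numbers of neighbours were chosen after seeing the data. No alternative moved the count of clusters past the adjusted threshold from 0 in limma, while the count at an unadjusted p below 0.05, 5 in the main analysis, ranged from 2 (without library 600, with at least 50 cells per cluster and with the nephron-lineage denominator) to 7 (without library 628). The smallest adjusted p ranged from 0.0862 (without library 628) to 0.646 (without library 600). The filter of 10 cells removed no cluster, so that its removal tests nothing. The centred log-ratio shifted the median cluster by -0.25, the nephron-lineage denominator by -0.32 and the denominator without phase clusters by -0.12 on the log2 scale. With the nephron-lineage denominator, 7 clusters were higher and 6 lower in dissected libraries, against 10 and 3 of the same clusters with all cells. Leaving out 1 library turned the progenitor class difference (range -12.6 to 2.82 percentage points), the podocyte difference (-0.97 to 14.5) and the log2 ratio of progenitors to early nephron (-0.74 to 0.32). The other class differences and ratios kept their sign under each alternative run. The stromal difference, -9.03 points, was -4.01 without c16, -6.14 without c26 and -1.12 without both. Of the 15 named clusters, 7 changed sign under some alternative. Leaving out a library gave ranges of -3.23 to 1.09 for NPC (c25), -1.24 to 0.018 for Interstitial Cell Lineages (c16), -0.49 to 2.73 for Podocyte (c20), -0.85 to 0.41 for Cap mesenchyme (c30), -0.25 to 0.52 for Differentiated NPC (c14), -0.82 to 1.38 for Proximal tubule (c6) and -0.22 to 0.73 for Proximal tubule (c7). Named clusters that kept their sign but moved by over 1.5 times without some library ranged from -1.89 to -0.18 for G2-M phase (c29), -0.83 to -0.17 for Proximal tubule (c18), 0.06 to 0.64 for Broad proximal diff (c17), 0.30 to 1.11 for Distal convoluted tubule (c10) and 0.87 to 1.82 for Loop of Henle (c15). With the nephron-lineage denominator, c14, c6 and c7 gave -0.23, -0.013 and -0.071, and c8, c17 and c18 0.29, 0.021 and -0.91 (0.59, 0.35 and -0.48 in the main analysis). With the centred log-ratio, c14, c7 and c8 gave -0.16, -0.012 and 0.32, the denominator without phase clusters gave -0.026 for c14, and the arcsine transform gave -0.0019 for c6 on its own scale. The causes were not tested. Where 1 dissected library was left out, the remaining one was assumed to vary like the vortexed libraries. The planned count models, the filter on genes per cell and the alternatives on depth and cell cycle were not run because the table has no such values. With 2 libraries against 3, exact tests cannot fall below 0.1, and sequencing depth is unknown. No paired analysis was possible because the preparations share no replicate numbers.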

Other observations

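The values and tests in this part were chosen after the data had been seen. Within the immune class, the libraries did not share 1 leading cluster, a difference that was not tested. Classical Monocyte (c35) was the largest immune cluster in library 627, at 41.8% of 450 immune cells, and pDC (c37) reached 16.7% there. In library 632, Monocyte (c34) led with 33.6% of 244 immune cells, and in library 628, Macrophage (c33) led with 35.0% of 180. Monocyte (c34) also led in library 623, with 28.6% of 154, and Classical Monocyte (c35) in library 600, with 26.6% of only 94. Endothelial cells were few, between 7 in library 632 and 79 in library 600, without Stromal-Microvascular (c4), which was placed in the stroma. Endothelial (c5) led in library 600 with 78.5% and in library 632 with 4 of 7 cells, and Endothelial cell (c3) in libraries 628, 623 and 627 with 56.9%, 64.7% and 78.3%. Intercalated cell (c9) came mostly from library 600, which supplied 76.5% of its cells, while Intercalated cell (c11) was spread more evenly, with 33.0% from library 600.

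In the embedding, NPC (c25) and Cap mesenchyme (c30), both names for nephron progenitors, lay apart. Stroma-named cells, mainly Fibroblast (c26), made up 81.2% ± 9.68 (SD, n = 5) of the neighbours of NPC (c25), against 24.1% of reference cells. Cap mesenchyme (c30) made up 1.51% ± 0.967, against 4.85%, and early nephron names 4.56% ± 3.55, against 17.0%. Of the neighbours of Cap mesenchyme (c30), Differentiated NPC (c19) made up 22.0% ± 7.80 and Collecting Duct (c13) 19.0% ± 17.8, with up to 45.6% in 1 library.

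Clusters that separated the preparations lay on 1 side. The shares of 11 of 37 clusters did not overlap between preparations, where chance gives 7.4, and all 11 were higher in dissected libraries. They were the endothelial clusters c2 and c5, Stromal-Microvascular (c4), Proximal tubule (c8), Intercalated cell (c11), Thick ascending limb (c12), Collecting Duct (c13), Loop of Henle (c15), Differentiated NPC (c19), Epithelial (c23) and B cell (c31), while Distal convoluted tubule (c10) and Intercalated cell (c9) overlapped. Of the 10 splits of the libraries, the real one included, 3 gave at least 11 such clusters, 10 splits are too few for a share under 0.05, and the highest other, 627 and 632 against the rest, gave 13. Overlap was counted on shares of all cells, where the median cluster had a log2 odds ratio of 0.25 in limma. With the centred log-ratio the median was -0.012.

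Library 600 differed from library 628, made the same way, in NPC (c25) and podocytes, among other clusters. Cap mesenchyme (c30), the other progenitor cluster, differed only 2.34-fold (2.02% in library 600 against 4.72%). Outside the nephron lineage, Intercalated cell (c9) made up 3.38% of library 600 against 0.253%, and Fibroblast (c21) 0.307% against 3.25%. Counting error does not account for the NPC (c25) difference, since the lower bound of its share in library 628 was 12.7 times the upper bound in library 600. A gain of podocytes alone does not, since the NPC (c25) share still differed 14.9-fold with podocytes left out, and a loss of NPC (c25) alone does not, since podocytes still differed 6.85-fold with that cluster left out. The preparation as labelled is the same for both libraries. Gestational age or the animal may underlie the differences and cannot be told apart, because the labels give an age for 0 of the libraries. Other causes were not tested.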
